A study of Danio rerio with 6 samples.

How the data were processed

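RNA was measured by high-throughput sequencing in whole zebrafish embryos at 3 days post fertilisation. Per the labels, each of the 6 libraries came from a pool of 15 embryos. The labels give 3 pools of embryos that carried a UAS-driven transgene for GFP fused to human EWSR1-ERG together with a pan-neuronal Gal4 driver and a UAS:Kaede reporter, and 3 pools of wild-type siblings. EWSR1-ERG is a fusion of an RNA-binding protein gene with an ETS transcription factor gene that occurs in Ewing sarcoma. The labels call the pools biological replicas; whether the pools came from separate clutches is not given in the sources used here. Whether the wild-type siblings carried the driver and reporter transgenes is not given either. The p-values therefore measure differences against the spread between these pools.

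The submitters' processing notes name Bowtie2, SAMtools, DESeq and the Zv9 genome build; their versions, their roles, the annotation release, the counting tool and the strand setting are not given in the sources used here. Each deposited file held, per Ensembl gene, the chromosome, the symbol, the identifier and the count of reads, with 31452 genes listed; gene coordinates were not used here. The values were treated as deposited expected counts per gene, because the last line of each file holds a number that is not whole. Every gene value was already whole, so rounding changes nothing. That last line matched the DESeq2 size factor recomputed from the counts, and it was not applied to the counts. The 2 lines per file that name no gene were left out. No count was found for 4527 genes, and 275 genes had no symbol. A spreadsheet had turned 21 symbols into dates, and names for these were taken from the gene name table by identifier. Symbols are as in the files except for 262 genes renamed by that table. Among them, the gene printed here as hsp70.1 stood in the files as mcm5. For 15 pairs of genes on the same chromosome the counts lay within 2% of each other in every library with at least 100 counts, as overlapping gene models that share reads would give, although the gene models were not examined. The human EWSR1-ERG sequence, GFP, Kaede and Gal4 are not among the genes listed, so expression of the transgene itself was not measured here.

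Genes were kept when edgeR's filterByExpr passed them with a minimum count of 10 and a minimum total of 15, which left 17557 tested genes. Library totals ran from 4771843 to 13338802 counts. A count of 0 in a library allows up to 3 counts, or 0.225 to 0.629 CPM; these limits cover counting error only. Counts were scaled by trimmed mean of M values (TMM) factors, which ran from 0.932 to 1.05, and CPM are counts relative to the scaled totals as edgeR computes them. EWSR1-ERG and wild-type pools were compared with edgeR's quasi-likelihood F test with robust estimation and Benjamini-Hochberg adjustment over all tested genes, at a threshold of 0.05. No covariate was used, since nothing in the labels matches replicate numbers between the groups. Fold changes are EWSR1-ERG over wild type. The standard error (SE) printed with a log2 fold change was its absolute value divided by the square root of the F statistic. It is thus an approximation derived from the test, not an error that the fit reports. CPM are given as mean ± SD over n = 3 pools per group. Ribosomal protein genes were taken by the symbol prefixes rps, rpl and rplp for the library shares, which lets in a few kinase genes of that prefix. Pairs of libraries were compared by a chi-square of each gene's counts against the library totals, averaged over genes, which is near 1 under sampling noise alone and grows with depth. Library totals and shares were compared with two-sided exact permutation tests, for which 3 pools against 3 can give no p below 0.1.

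A total of 30 gene lists with 999 entries was fixed before the data were examined, as were the tests, the rule for named genes and 21 alternative settings. The lists cover mitosis, DNA replication, p53 targets, apoptosis, pan-neuronal and synaptic genes, excitatory neurons, inhibitory neurons, monoamine and peptide neurons, neural progenitors, oligodendrocytes and myelin, neural crest and pigment cells, photoreceptors, lens, skeletal muscle, heart, endothelium, erythroid cells, myeloid cells and microglia, inflammation, orthologs of genes reported as raised by EWSR1-ETS fusions, orthologs of genes reported as lowered by them, endogenous FET and ETS family genes, cartilage and bone matrix, epidermis, liver with gut and pancreas, heat shock and unfolded protein response, sterol synthesis, clock and glucocorticoid response, targets of the Hedgehog, Wnt and Notch pathways, and axon guidance and adhesion. Of the entries, 958 were matched by symbol, alias or the reference tables and 41 were not. The tested lists held 851 distinct genes, 34 of them in more than 1 list. Each list was tested against all other genes with limma's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 30 lists. Camera with an estimated correlation and limma's fry were run beside it. Fry tests whether the members of a list move, on balance, one way, and compares them with no other genes.

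The named genes are the 12 with the largest positive and the 12 with the largest negative log2 fold change among genes past the threshold that had a mean of at least 2 CPM, a usable symbol and no overlap between the groups. A further 10 genes that ranked among the higher ones and 1 among the lower ones had no usable symbol. The rule also takes erg, ewsr1a and ewsr1b, up to 3 changed members of each list by smallest p (for a list without a changed member, the 1 member with the smallest p), and the 3 genes with the smallest p in each direction. Genes named outside this rule are marked as chosen after their values were seen. Gene families described in the closing section were chosen after the data had been seen.

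The alternatives were other scalings, other filters on low counts, DESeq2, limma-voom, a fit without robust estimation, a block for the replicate number, a test against 1.5-fold, leaving out each library in turn, other list tests, and lists without shared genes. A further 3 were added after the data had been seen. Transcripts were not tested, since the files hold genes. The tests were also tested on simulated data with the levels and spread of these libraries. Over 10 draws with 200 changed genes each among 17557, the edgeR test recovered 32.1% of the genes changed 1.5-fold, 71.8% of those changed 2-fold and 96.2% of those changed 4-fold, and 8.59% of its calls were false. In simulated lists, camera gave an adjusted p of 8.99e-60 for a list of 33 changed genes, 0.000946 with an estimated correlation, and fry gave 1.52e-05. The simulated genes were drawn independently, so these values do not show how the list tests behave when genes of a list are correlated. A smaller share of genes was changed in the simulation than was called in these libraries, so the recovered and false shares may differ here. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.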

Results

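Gene expression was profiled in 6 libraries of whole embryos at 3 days post fertilisation, each from a pool of 15 embryos. In 3 pools the embryos expressed EWSR1-ERG in neurons, and the other 3 pools were wild-type siblings. The comparison between them asks which genes the fusion protein changes when it is made in the nervous system of a developing fish. Whether the wild-type siblings carried the Gal4 and Kaede transgenes is not given in the sources used here, so the comparison does not separate the fusion protein from those transgenes. The wild-type libraries held 5672149, 5154500 and 4771843 counts, and the EWSR1-ERG libraries 6474430, 5611197 and 13338802 counts. EWSR1-ERG replicate 3 was thus the deepest library, and its label names another sequencing lane than the other 5. The exact permutation p for the totals was 0.2 (n = 3 per group), where 3 pools against 3 allow no p below 0.1, so a difference in depth between the groups stays open.

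Mitochondrially encoded genes took 4.08% ± 0.243 (SD, n = 3) of the counts in wild-type pools and 2.82% ± 0.176 (SD, n = 3) in EWSR1-ERG pools. The groups did not overlap in this share, and the exact permutation p of 0.1 is the smallest that 3 pools against 3 allow. Ribosomal protein genes took 8.31% ± 0.704 and 8.72% ± 0.276 of the counts (exact permutation p = 0.5, n = 3 per group). The 50 most abundant genes took 26.1% ± 1.79 in wild-type pools and 25.9% ± 0.914 in EWSR1-ERG pools (exact permutation p = 1, n = 3 per group).

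**Figure D1:**
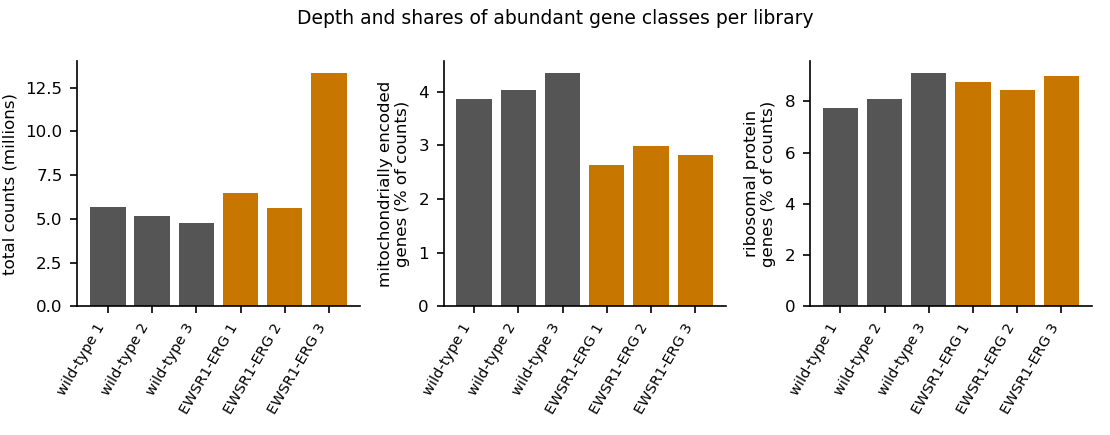
Bars give, for each of the 6 libraries, the total counts, the percent of counts in mitochondrially encoded genes and the percent in ribosomal protein genes. EWSR1-ERG replicate 3 stands at 13338802 counts, and the mitochondrial share of the wild-type libraries, from 3.87% to 4.35%, lies above that of the EWSR1-ERG libraries, from 2.64% to 2.99%.

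Many genes of photoreceptors, neurons, pigment cells, liver and pancreas were lower in embryos with neuronal EWSR1-ERG, and many genes of macrophages and neutrophils, heat shock, blood and vessels were higher. Of 38 photoreceptor genes tested, 36 fell, with a median log2 fold change of -2.36, which is 5.15-fold lower. The ultraviolet cone opsin gene opn1sw1 (ENSDARG00000045677, chromosome 4 of Zv9) fell from 1702 ± 102 to 194 ± 9.89 CPM (SD, n = 3 per group). Of 31 myeloid genes tested, 25 rose, with a median 2.9-fold higher. The inducible heat shock gene hsp70l (ENSDARG00000055723, chromosome 8) rose from 7.58 ± 1.80 to 74.4 ± 10.9 CPM (SD, n = 3 per group).

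By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1309 genes were higher and 1732 lower in EWSR1-ERG pools among 17557 tested, or 17.3% of them. At least a 2-fold change was seen in 435 of the higher and 721 of the lower genes. The groups did not overlap in 1296 of the higher and 1706 of the lower genes, and in 35.1% of all tested genes, against 10% by chance. Without wild-type replicate 1 the counts were 718 higher and 1135 lower, and without wild-type replicate 2 they were 646 and 981. Tested against a change of 1.5-fold, 294 genes were higher and 484 lower.

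**Figure D2:**
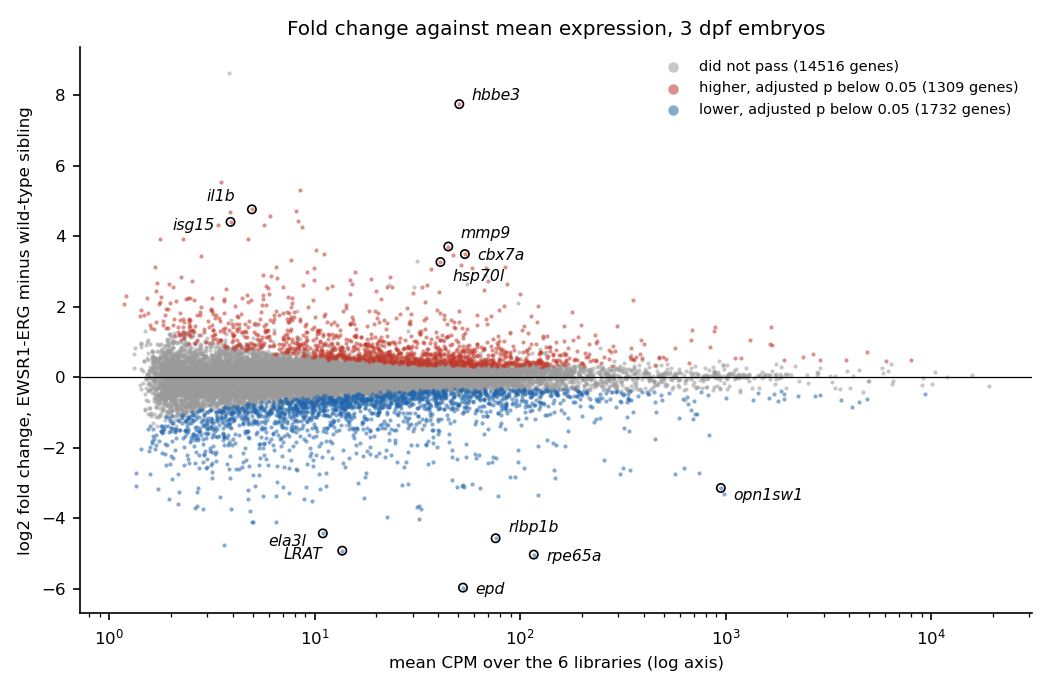
Each point is 1 of 17557 tested genes, with the mean CPM over the 6 libraries on a logarithmic horizontal axis and the log2 fold change of EWSR1-ERG over wild type on the vertical axis. Red points are the 1309 higher genes, blue points the 1732 lower genes and grey points the rest; circled genes range from epd at -5.96 to hbbe3 at 7.75.

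The largest log2 fold change among the higher genes was that of hbbe3 (ENSDARG00000038147, chromosome 12), an embryonic beta globin gene, at 7.75 (SE 0.674, adjusted p = 0.000381). It stood at 0.479 ± 0.375 CPM in wild-type pools, where it had 7 counts in total, and at 101 ± 43.8 CPM in EWSR1-ERG pools (SD, n = 3 per group). The beta globin gene hbbe2 on the same chromosome, chosen after its value was seen, stood at 0.21 (adjusted p = 0.433). The Polycomb chromobox gene cbx7a (ENSDARG00000038025, chromosome 3) rose from 8.68 ± 0.308 to 99.1 ± 35.5 CPM (log2 fold change 3.50, SE 0.274, adjusted p = 2.17e-05). The chemokine gene ccl34a.4 (ENSDARG00000090873), which the files list as si:ch211-122l24.4, rose by 4.31 on the log2 scale (SE 0.404, adjusted p = 5.35e-06) and the interferon-stimulated gene isg15 by 4.41 (SE 0.583, adjusted p = 0.000196), from 8 and 5 wild-type counts in total. The remaining higher genes of the 12 were il1b, a proinflammatory cytokine (4.77, adjusted p = 0.0394), fosl1a, an AP-1 transcription factor (4.70, adjusted p = 0.0154), ms4a17a.2 (4.57, adjusted p = 0.0038), mmp9, a matrix metalloproteinase (3.71, adjusted p = 0.0491), ms4a17a.1 (3.61, adjusted p = 0.00864), irg1l (3.47, adjusted p = 0.0196), ppp1r27 (3.44, adjusted p = 5.93e-05) and hsp70l (3.27, adjusted p = 1.71e-08). Of these, il1b, fosl1a, ms4a17a.2 and ppp1r27 had 5, 4, 7 and 7 counts in total in the wild-type pools.

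Among these genes, some calls ended when a single library was left out. Those of il1b, mmp9 and irg1l ended whichever wild-type pool was left out, so no single wild-type pool decided them. The calls of il1b (log2 fold change 6.24), fosl1a (4.98), mmp9 (3.58), ms4a17a.1 (3.35) and irg1l (3.49) ended without wild-type replicate 1. Those of il1b (4.21), mmp9 (3.84) and irg1l (3.47) ended without wild-type replicate 2, and those of il1b (4.62), fosl1a (4.24), mmp9 (3.72) and irg1l (3.45) without wild-type replicate 3. With no filter on low counts the calls of il1b, fosl1a, mmp9 and ms4a17a.1 also ended, and with a filter of at least 1 CPM in 3 libraries those of il1b and mmp9. EWSR1-ERG replicate 1 stood above the other pools of its group in several of these genes, with mmp9 at 165 CPM against 43.0 and 41.6 CPM and il1b at 20.1 CPM against 4.90 and 3.84 CPM. Without it the calls held at smaller log2 fold changes for il1b (3.65), fosl1a (3.73), ms4a17a.2 (3.85), mmp9 (2.75), ms4a17a.1 (2.96) and irg1l (2.77). Each of these calls had a smaller adjusted p without that library than with all 6 libraries. Without wild-type replicate 3 the values of hbbe3 (8.47) and ms4a17a.2 (5.29) moved by over 1.5-fold, as did that of isg15 (5.11) without wild-type replicate 2.

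The largest decrease was in epd (ENSDARG00000014745, chromosome 5), which encodes the brain glycoprotein ependymin and stood at 104 ± 9.86 CPM in wild-type and 1.61 ± 0.333 CPM in EWSR1-ERG pools (log2 fold change -5.96, SE 0.169, adjusted p = 7.92e-11). This was 62.3-fold lower. Among the others, the products of rpe65a (ENSDARG00000007480, chromosome 2), LRAT and rlbp1b act in the visual cycle, which regenerates the retinal chromophore. Expression of rpe65a fell from 227 ± 39.8 to 6.57 ± 3.90 CPM (-5.02, SE 0.383, adjusted p = 0.000146), LRAT from 26.5 ± 6.86 to 0.752 ± 0.548 CPM (-4.91, SE 0.345, adjusted p = 1.18e-06) and rlbp1b from 146 ± 20.9 to 6.15 ± 3.29 CPM (-4.56, SE 0.282, adjusted p = 5.1e-06). The retinal G protein-coupled receptor gene rgra fell by 3.96 on the log2 scale (adjusted p = 3.2e-06), and guca1g, which encodes a guanylate cyclase activator, by 3.74 (adjusted p = 3.06e-05). The digestive enzyme genes ela3l, an elastase, and amy2a, an amylase, fell by 4.42 (adjusted p = 1.54e-08) and 4.11 (adjusted p = 1.34e-05). The G protein subunit gene gng8 fell by 4.76 (adjusted p = 1.26e-06), with 6 counts in total in the EWSR1-ERG pools. The other lower genes of the 12 were FHL5 (-4.11, adjusted p = 1.24e-06), TGM1 (1 of 6), a transglutaminase (-4.10, adjusted p = 1.26e-06), and scpp9 (-3.80, adjusted p = 0.000105). Among these, amy2a (-4.85) and guca1g (-4.49) moved by over 1.5-fold without EWSR1-ERG replicate 2, and LRAT (-5.68), TGM1 (1 of 6) (-4.79) and scpp9 (-5.63) without EWSR1-ERG replicate 3.

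The smallest p-values among higher genes belonged to si:dkey-8k3.2 (log2 fold change 3.12, SE 0.147, adjusted p = 5.8e-09), c6.2, a complement component gene listed as c6 in the files (3.2, SE 0.158, adjusted p = 9.52e-09), and hsp70l. Among lower genes they belonged to epd, to rbp3, listed as irbp in the files, which encodes the interphotoreceptor retinoid-binding protein and fell from 114 ± 6.60 to 13.2 ± 0.903 CPM (-3.12, SE 0.117, adjusted p = 1.92e-09), and to opn1sw1 (-3.14, SE 0.124, adjusted p = 2.43e-09).

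**Figure D3:**
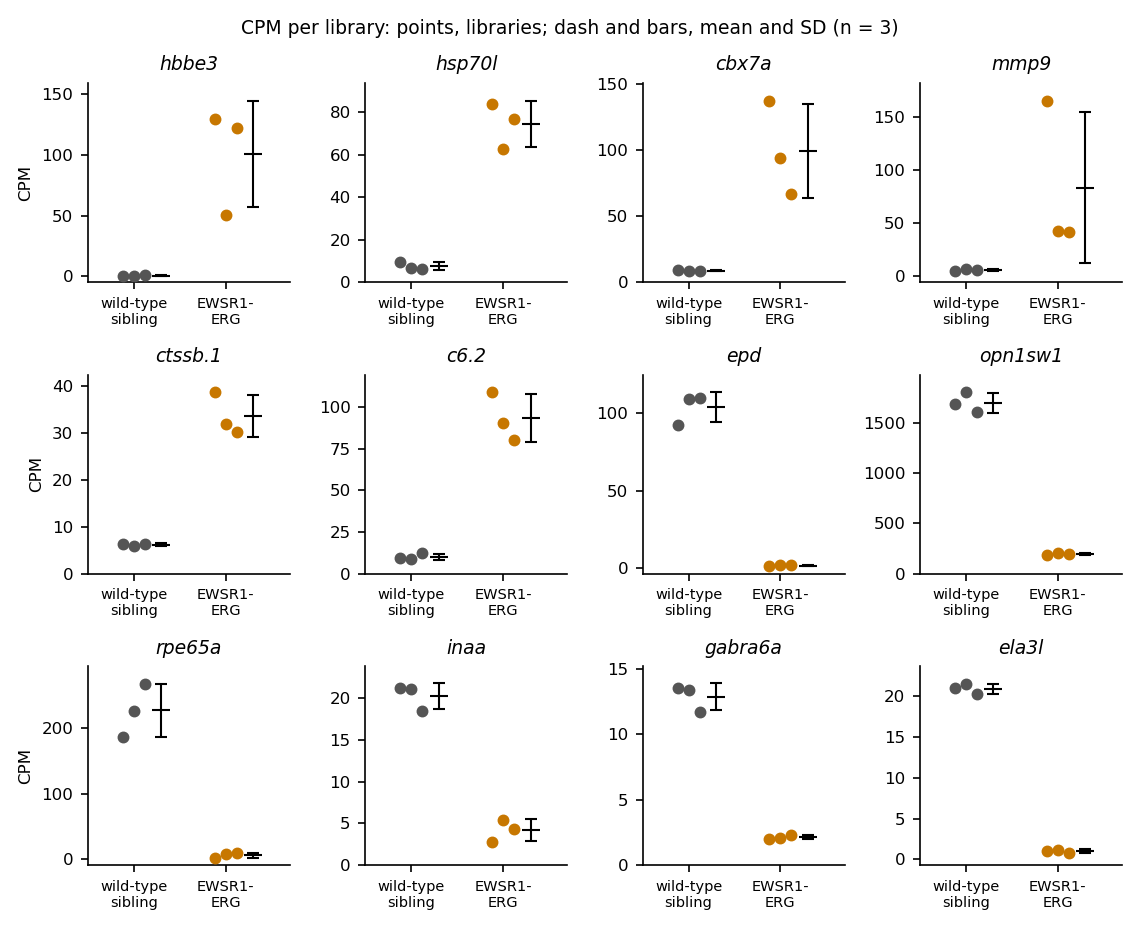
Points give the CPM of each of the 6 libraries on a linear axis for 12 genes, with a dash and bars for the mean and SD of the 3 pools of each group. For hbbe3, hsp70l, cbx7a, mmp9, ctssb.1 and c6.2 every EWSR1-ERG pool lies above every wild-type pool, and for epd, opn1sw1, rpe65a, inaa, gabra6a and ela3l every EWSR1-ERG pool lies below.

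The 30 gene lists place these genes among their tissues and pathways. By camera, 18 lists were shifted against all other genes, 7 upward and 11 downward. With an estimated correlation none of the 18 calls held, and 6 lists had an unadjusted p under 0.05. Fry called 16 lists: all of the 18 except those of apoptosis, pan-neuronal genes, monoamine neurons and neural progenitors, and also the endogenous FET and ETS genes and the orthologs of genes reported as lowered by EWSR1-ETS fusions. These shifts stand beside the lower mitochondrial share of counts in EWSR1-ERG pools and the greater depth of EWSR1-ERG replicate 3. Within the groups, counts differed most from the other pools in EWSR1-ERG replicate 1, with a chi-square per gene of 6.82 and 10.8 against 3.35 between the other 2, and in wild-type replicate 3, with 7.12 and 4.79 against 1.72.

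**Figure D4:**
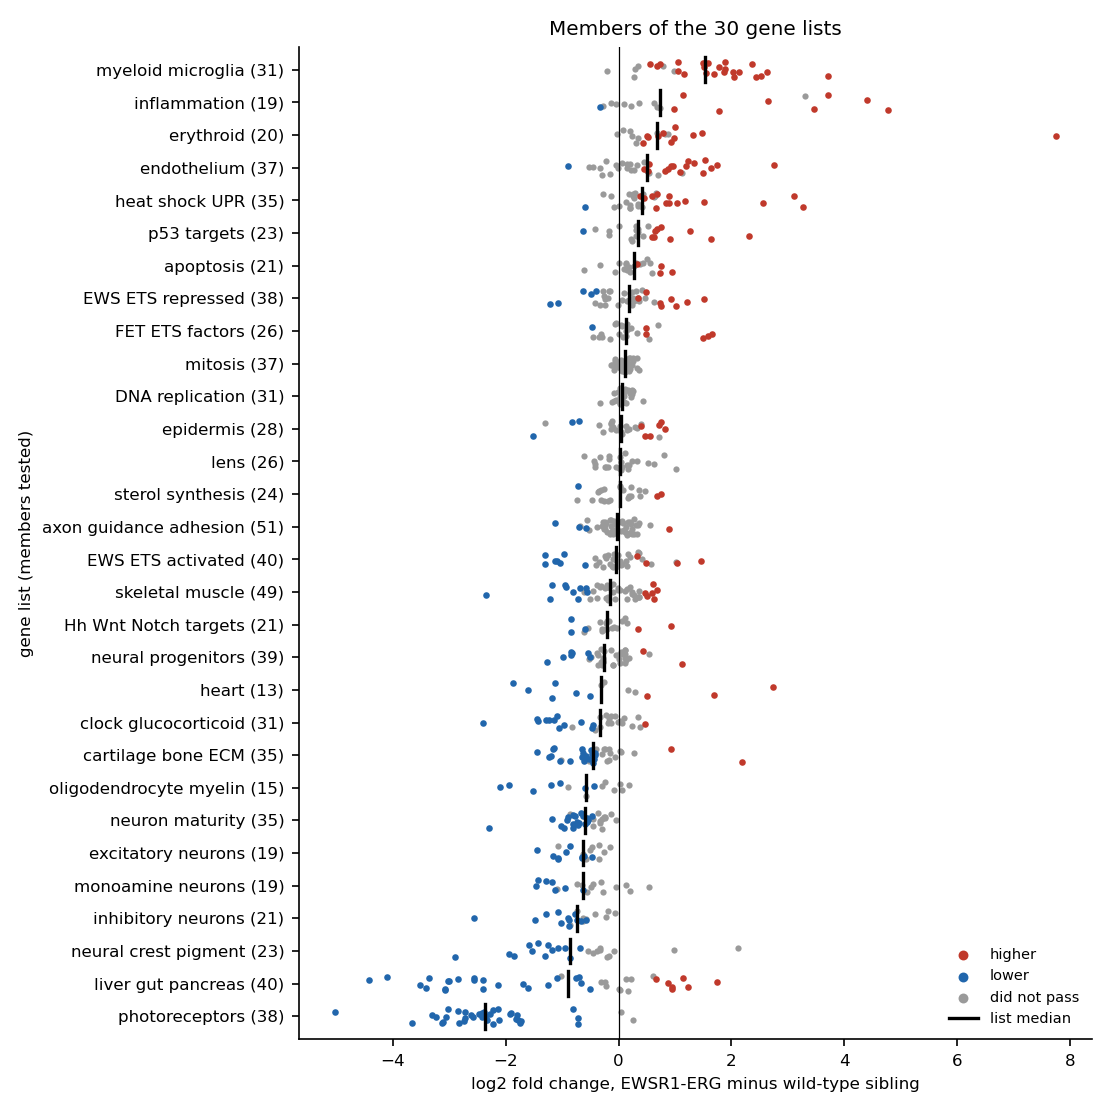
Each point is a tested gene of 1 of 30 lists, placed by its log2 fold change of EWSR1-ERG over wild type, with a black bar at the median of each list. Medians run from -2.36 for photoreceptors to 1.54 for myeloid cells and microglia.

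In the retina, 36 of 38 photoreceptor genes fell, as did 36 when adjusted over the list alone, and the other 2 did not pass (camera adjusted p = 1.08e-35, adjusted p = 0.189 with an estimated correlation). After opn1sw1, the smallest p-values were those of the green cone opsin opn1mw1, which fell from 985 ± 34 to 149 ± 2.88 CPM (-2.73, SE 0.114, adjusted p = 2.43e-09), and of prph2b, a peripherin of the outer segment disc (-2.84, SE 0.120, adjusted p = 2.43e-09). The members that did not pass, named after their values were seen, were opn1mw2 at 0.26 (adjusted p = 0.358) and gnb1b at 0.05 (adjusted p = 0.798). The list also holds rpe65a, a gene of the pigment epithelium. In the lens, 26 crystallin and membrane genes had a median of 0.03, and by edgeR none passed at either adjustment, adjusted over the list alone included (camera adjusted p = 0.775). At an unadjusted p under 0.05 stood 3 of them; DESeq2 called 0 and limma-voom 1. The lens gene with the smallest p was crygs3 at 1.01 (SE 0.348, adjusted p = 0.0664), which passed without EWSR1-ERG replicate 2 (1.21) and with no filter on low counts.

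By camera, the lists of pan-neuronal genes and of inhibitory, excitatory, and monoamine and peptide neurons were shifted downward. Of 35 pan-neuronal and synaptic genes, 21 fell and the other 14 did not pass, and 24 fell when adjusted over the list alone. Their median was -0.60 (camera adjusted p = 7.48e-09, adjusted p = 0.375 with an estimated correlation). The neuronal intermediate filament gene inaa fell from 20.3 ± 1.5 to 4.16 ± 1.34 CPM (-2.29, SE 0.208, adjusted p = 4.04e-06), the synaptophysin gene sypb from 165 ± 7.30 to 72.5 ± 8.69 CPM (-1.19, SE 0.112, adjusted p = 6.01e-06) and the synaptic vesicle gene rab3aa by 1.01 (adjusted p = 9.02e-05). Among 21 genes of inhibitory neurons, 12 fell, or 15 when adjusted over the list alone, with a median of -0.74 (camera adjusted p = 7.56e-08, adjusted p = 0.281 with an estimated correlation). The GABA receptor gene gabra6a fell from 12.9 ± 0.987 to 2.13 ± 0.159 CPM (-2.57, SE 0.216, adjusted p = 1.99e-06), and the calcium-binding protein genes pvalb7 and calb2b fell by 1.28 (adjusted p = 2.21e-05) and 1.47 (adjusted p = 4.96e-05).

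Among 19 genes of excitatory neurons, 10 fell, or 12 when adjusted over the list alone, with a median of -0.62 (camera adjusted p = 1.25e-06, adjusted p = 0.336 with an estimated correlation). Examples were the forebrain transcription factor genes eomesa (-1.45, SE 0.189, adjusted p = 0.000121) and tbr1b (-1.16, SE 0.199, adjusted p = 0.00107) and the vesicular glutamate transporter gene slc17a6b (-0.64, SE 0.121, adjusted p = 0.00208). Of 19 genes of monoamine and peptide neurons, 7 fell, or 8 when adjusted over the list alone, with a median of -0.63 (camera adjusted p = 0.00024, adjusted p = 0.333 with an estimated correlation). They included the neuropeptide gene tac1 (-1.19, SE 0.242, adjusted p = 0.00395), ddc, whose product makes dopamine and serotonin (-1.28, SE 0.277, adjusted p = 0.00567), and tph2 of serotonin synthesis (-1.43, SE 0.355, adjusted p = 0.0127). The call of ddc ended without wild-type replicate 2 (-1.11), and that of tph2 without wild-type replicate 1 (-1.19), wild-type replicate 2 (-1.34) or EWSR1-ERG replicate 3 (-1.20).

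Of 39 neural progenitor and glial genes, 7 fell, 2 rose and 30 did not pass; 10 fell and 2 rose when adjusted over the list alone. The median was -0.26 (camera adjusted p = 0.0224, adjusted p = 0.414 with an estimated correlation). The glial glutamate transporter gene slc1a2b fell from 469.7 ± 41 to 237 ± 41.3 CPM (-0.99, SE 0.136, adjusted p = 0.000188), and the Notch target her4.2 and the gap junction gene cx43 fell by 0.84 (adjusted p = 0.00127) and 0.83 (adjusted p = 0.00154). The 2 higher members, named after their values were seen, were the intermediate filament genes nes (1.12, adjusted p = 0.00363) and vim (0.44, adjusted p = 0.00791). This list lost its call without EWSR1-ERG replicate 2 (median -0.18), by fry and with genes of more than 1 list left out. Of 15 oligodendrocyte and myelin genes, 7 fell, or 9 when adjusted over the list alone, with a median of -0.58 (camera adjusted p = 0.000124, adjusted p = 0.333 with an estimated correlation). The myelin protein genes plp1b (-2.09, SE 0.193, adjusted p = 4.76e-06), mpz (-1.94, SE 0.240, adjusted p = 7.9e-05) and mbpa (-1.52, SE 0.193, adjusted p = 0.000239) were the examples.

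Of 23 neural crest and pigment cell genes, 13 fell and 10 did not pass, with a median of -0.87; adjusted over the list alone, 15 fell and 2 rose (camera adjusted p = 1.11e-07, adjusted p = 0.333 with an estimated correlation). The melanosome matrix gene pmelb fell from 83.0 ± 10.8 to 10.6 ± 5.11 CPM (-2.9, SE 0.286, adjusted p = 0.000171). The iridophore gene pnp4a fell by 1.86 (adjusted p = 1.11e-06) and the melanosome transporter gene slc45a2 by 1.58 (adjusted p = 0.000138). Further members were named after their values were seen. The transcription factor genes sox10 (-0.08, adjusted p = 0.701), tfap2a (-0.17, adjusted p = 0.259) and foxd3 (-0.45, adjusted p = 0.0535) did not pass, while mitfa fell (-1.18, adjusted p = 0.00393). Positive values, which did not pass over all genes, were those of aox3 (2.11, adjusted p = 0.0663) and csf1ra (0.99, adjusted p = 0.0593).

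Myeloid genes formed the list with the highest median, at 1.54. Of 31 tested, 25 rose and 6 did not pass, and 29 rose when adjusted over the list alone (camera adjusted p = 2.38e-20, adjusted p = 0.189 with an estimated correlation). The cathepsin S gene ctssb.1 rose from 6.13 ± 0.283 to 33.6 ± 4.54 CPM (2.44, SE 0.165, adjusted p = 2.2e-07), the macrophage gene mfap4 by 2.37 (adjusted p = 3.28e-06) and the leukocyte plastin gene lcp1 by 1.89 (adjusted p = 6.98e-06). Of 19 inflammation and interferon genes, 8 rose, 1 fell and 10 did not pass, with a median of 0.73; 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 6.12e-06, adjusted p = 0.228 with an estimated correlation). The cytokine signalling inhibitor gene socs3b rose from 23.8 ± 2.36 to 150 ± 35.8 CPM (2.65, SE 0.172, adjusted p = 5.06e-07) and stat3 rose by 1.15 (adjusted p = 0.000316), beside isg15. The lower member, named after its value was seen, was nfkbiab, which encodes an inhibitor of NF-kappaB (-0.33, adjusted p = 0.0377).

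Stress gene lists were shifted upward. Of 35 heat shock and unfolded protein response genes, 14 rose, 1 fell and 20 did not pass, with a median of 0.41; 18 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.34e-07, adjusted p = 0.336 with an estimated correlation). Beside hsp70l, the heat shock gene hsp70.1 rose from 14.1 ± 3.78 to 123 ± 26.7 CPM (3.11, SE 0.206, adjusted p = 1.59e-06) and the stress-induced transcription factor gene atf3 from 9.55 ± 0.683 to 57.2 ± 14.7 CPM (2.56, SE 0.191, adjusted p = 1.18e-06). The lower member, chosen after its value was seen, was chac1 (-0.60, adjusted p = 0.000919). Of 23 p53 target genes, 9 rose, 1 fell and 13 did not pass, with a median of 0.35; 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 6.64e-05, adjusted p = 0.282 with an estimated correlation). The sestrin gene sesn1 rose from 159 ± 3.96 to 255 ± 37.3 CPM (0.69, SE 0.120, adjusted p = 0.00123), the TNF receptor gene tnfrsf1a by 1.64 (adjusted p = 0.00241) and plk2b by 0.63 (adjusted p = 0.00312). The lower member, chosen after its value was seen, was the cyclin-dependent kinase inhibitor gene cdkn1a (-0.64, adjusted p = 0.022).

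Of 21 apoptosis genes, 4 rose and 17 did not pass, with a median of 0.28; 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.336 with an estimated correlation). The survival gene mcl1a rose by 0.94 (SE 0.134, adjusted p = 0.000239), the apoptosome gene apaf1 by 0.74 (SE 0.163, adjusted p = 0.00641) and the initiator caspase gene casp8 by 0.75 (SE 0.184, adjusted p = 0.0124). The remaining higher member, named after its value was seen, was the effector caspase gene casp3a (0.33, adjusted p = 0.0382). The call of apaf1 ended without wild-type replicate 2 (0.61) and that of casp8 without wild-type replicate 1 (0.63).

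Blood and vessel lists were shifted upward. Of 20 erythroid genes, 11 rose and 9 did not pass, with a median of 0.69, and 14 rose when adjusted over the list alone (camera adjusted p = 4.84e-08, adjusted p = 0.228 with an estimated correlation). The alpha globin gene hbae1.3 rose from 502 ± 108 to 1258 ± 120.0 CPM (1.33, SE 0.152, adjusted p = 3.65e-05), the haem synthesis gene alas2 by 1.00 (adjusted p = 5.88e-05) and the anion exchanger gene slc4a1a by 0.99 (adjusted p = 0.000206). Of 37 endothelial genes, 16 rose, 1 fell and 20 did not pass, with a median of 0.50; 21 rose and 2 fell when adjusted over the list alone (camera adjusted p = 5.02e-06, adjusted p = 0.189 with an estimated correlation). The tight junction gene cldn5b rose from 22.7 ± 1.6 to 70.0 ± 4.65 CPM (1.63, SE 0.116, adjusted p = 3.67e-07) and vsg1, a vessel gene, by 1.09 (adjusted p = 4.74e-05). The gene ENSDARG00000075833, which has no symbol in the files and is lyve1a in the gene name table, rose by 2.76 (adjusted p = 8.28e-05). The lower member, chosen after its value was seen, was the angiopoietin receptor gene tek (-0.90, adjusted p = 0.0319).

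Of 40 liver, gut and pancreas genes, 23 fell, 7 rose and 10 did not pass, with a median of -0.89; 23 fell and 8 rose when adjusted over the list alone (camera adjusted p = 3.35e-06, adjusted p = 0.228 with an estimated correlation). The pancreatic elastase genes ela3l and ela2 fell, the latter from 32.1 ± 3.61 to 2.88 ± 0.699 CPM (-3.42, SE 0.191, adjusted p = 3.22e-08), and the transferrin gene tfa fell from 1069 ± 47.4 to 181 ± 37.2 CPM (-2.56, SE 0.148, adjusted p = 4.39e-08). Among members named after their values were seen, the liver genes fabp10a (-3.07, adjusted p = 0.00125) and ttr (-3.07, adjusted p = 1.37e-05) fell. The 7 higher members, also named after their values were seen, were the fibrinogen genes fgg (0.95, adjusted p = 9.15e-05), fga (0.88, adjusted p = 0.000202) and fgb (0.66, adjusted p = 0.00393), the ceruloplasmin gene cp (1.75, adjusted p = 0.000226), the apolipoprotein gene apobb (0.95, adjusted p = 0.00013) and the hormone genes sst2 (1.14, adjusted p = 0.000137) and gcga (1.23, adjusted p = 0.000152).

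Of 35 cartilage and bone matrix genes, 19 fell, 2 rose and 14 did not pass, with a median of -0.44; 22 fell and 2 rose when adjusted over the list alone (camera adjusted p = 6.12e-06, adjusted p = 0.333 with an estimated correlation). The proteoglycan gene epyc fell from 237 ± 23.3 to 106 ± 10.5 CPM (-1.16, SE 0.117, adjusted p = 1.07e-05). The 2 higher members were fibronectin genes: fn1b rose from 126 ± 6.29 to 579 ± 165 CPM (2.2, SE 0.174, adjusted p = 3.28e-06) and fn1 by 0.94 (adjusted p = 3.23e-05). Of 31 clock and glucocorticoid response genes, 12 fell, 1 rose and 18 did not pass, with a median of -0.32; 13 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.000194, adjusted p = 0.336 with an estimated correlation). The clock repressor gene nr1d1 fell from 63.5 ± 9.75 to 11.9 ± 1.34 CPM (-2.41, SE 0.144, adjusted p = 6.34e-08), nr1d2a fell by 1.24 (adjusted p = 2.98e-05), and the glucocorticoid-induced gene fkbp5 fell from 92.7 ± 7.48 to 37.7 ± 1.80 CPM (-1.29, SE 0.108, adjusted p = 1.83e-06). The higher member, chosen after its value was seen, was tefa (0.46, adjusted p = 0.0107).

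The endogenous partner genes and the lists of reported target genes were not called. Endogenous ewsr1a stood at 173, 156 and 163 CPM in wild-type and 164, 159 and 192 CPM in EWSR1-ERG pools (0.07, adjusted p = 0.733), a direction that turned without EWSR1-ERG replicate 3 (-0.022). Its paralog ewsr1b stood at 107, 114 and 117 CPM and at 116, 117 and 125 CPM (0.08, adjusted p = 0.627). Endogenous erg stood at 2.71, 1.35 and 2.94 CPM and at 1.53, 1.57 and 1.84 CPM (-0.46, SE 0.363, adjusted p = 0.442). Of 40 orthologs of genes reported as raised by EWSR1-ETS fusions, 4 rose, 7 fell and 29 did not pass, also when adjusted over the list alone, with a median of -0.05 (camera adjusted p = 0.699). The kinase gene jak1 rose by 1.04 (adjusted p = 2.58e-05), while nr4a1 (-1.31, adjusted p = 1.94e-05) and cck (-1.09, adjusted p = 0.00437) fell. The remaining higher members, named after their values were seen, were myca (0.49), ccnd1 (0.33) and CT573348.1 (1.47), which is tnfrsf11a in the gene name table. Of 38 orthologs of genes reported as lowered, 8 rose, 5 fell and 25 did not pass, with a median of 0.19; 12 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.115). With genes of more than 1 list left out this list was called (median 0.24). The filamin gene flna rose 2.03-fold (adjusted p = 0.000202), while lox, a collagen crosslinking enzyme, fell by 1.22 (adjusted p = 0.000437). The remaining lower members, named after their values were seen, were acta2 (-1.08), cdkn1a (-0.64), col1a1a (-0.49) and spry2 (-0.39).

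Of 26 endogenous FET and ETS family genes, 5 rose, 1 fell and 20 did not pass, with a median of 0.13; 6 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.051). This list was called when any one of the 6 libraries was left out, at medians from 0.09 without wild-type replicate 2 to 0.15 without wild-type replicate 3, and also with the other filters on low counts, library totals only and EWSR1-ERG replicate 3 thinned. The myeloid ETS genes spi1b (1.5, SE 0.193, adjusted p = 0.000102) and spi1a (1.58, SE 0.224, adjusted p = 0.000224), which also stand in the myeloid list, and the epithelial ETS gene elf3 (1.65, SE 0.194, adjusted p = 0.000121) rose. With genes of more than 1 list left out, spi1a and spi1b among them, the FET and ETS list was not called. Members named after their values were seen were elk3 (0.49) and ef1 (0.48, elf1 in the gene name table), which rose, and etv5b (-0.46, adjusted p = 0.0107), which fell.

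Cell cycle genes were not called. By edgeR's test with Benjamini-Hochberg adjustment, the 37 mitosis genes had a median of 0.11 (camera adjusted p = 0.112) and 0 passed, adjusted over the list alone or over all genes; 2 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The 31 DNA replication genes had a median of 0.07 (camera adjusted p = 0.213) and 0 passed by edgeR, adjusted over the list alone or over all genes, nor by DESeq2 or limma-voom; 0 had an unadjusted p under 0.05. The smallest p in each belonged to cenpe at 0.34 (adjusted p = 0.0766) and cdc45 at 0.44 (adjusted p = 0.178). Without wild-type replicate 3 the mitosis list was called (median 0.14), and without EWSR1-ERG replicate 2 both lists were (medians 0.16 and 0.12).

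Muscle, heart and skin lists held changed genes in both directions. Of 49 skeletal muscle genes, 10 fell, 6 rose and 33 did not pass, with a median of -0.15; 13 fell and 8 rose when adjusted over the list alone (camera adjusted p = 0.121). The slow troponin gene tnnt1 fell by 2.36 (adjusted p = 1.32e-06), pgam2 by 0.93 (adjusted p = 9.92e-05) and the fast troponin gene tnni2a.1 by 1.18 (adjusted p = 0.000153); without EWSR1-ERG replicate 3 the list was called (median -0.22). Of 13 heart genes, 6 fell, 3 rose and 4 did not pass, with a median of -0.31; 7 fell and 3 rose when adjusted over the list alone (camera adjusted p = 0.131). DESeq2, which tests 19 members of this list, gave a median of -0.079 over those and -0.31 over the 13. The ventricular myosin genes vmhc, from 55.4 ± 4.34 to 14.6 ± 4.81 CPM (-1.88, SE 0.190, adjusted p = 3.1e-05), and vmhcl (-1.6, adjusted p = 2.82e-05) fell, and the natriuretic peptide gene nppa rose from 9.47 ± 0.902 to 30.7 ± 2.71 CPM (1.7, SE 0.148, adjusted p = 2.92e-06). The other higher heart members, named after their values were seen, were BX323876.3 (2.74), which is nppb in the gene name table, and gata5 (0.50). Of 28 epidermis genes, 6 rose, 3 fell and 19 did not pass, with a median of 0.05; 7 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.461). The keratin gene krt1-19d fell from 255 ± 28.6 to 89.2 ± 9.56 CPM (-1.52, SE 0.121, adjusted p = 1.22e-06), the periplakin gene ppl fell by 0.70 (adjusted p = 0.000958) and the ionocyte gene foxi3a rose by 0.82 (adjusted p = 0.00217); the remaining lower member, named after its value was seen, was krt1-c5 (-0.82). Without wild-type replicate 3 this list was called (median 0.31).

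Lists of axon guidance, signalling targets and sterol synthesis were not called. Of 51 axon guidance and adhesion genes, 3 fell, 1 rose and 47 did not pass, with a median of -0.02; 2 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.925). The netrin gene ntn1b fell by 1.12 (adjusted p = 0.00645) and the contactin gene cntn1b by 0.71 (adjusted p = 0.0227), and the ephrin receptor gene epha2 rose by 0.89 (adjusted p = 0.0143). The remaining lower member, named after its value was seen, was the semaphorin gene sema6d (-0.57). Of 21 targets of the Hedgehog, Wnt and Notch pathways, 3 fell, 2 rose and 16 did not pass, also when adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0695); the list was called without EWSR1-ERG replicate 3 (median -0.28), with the replicate number as a block (-0.20) and with no filter on low counts (-0.19). The Notch target her4.1 fell by 0.84 (adjusted p = 0.0143), beside her4.2, and the Wnt inhibitor gene dkk1b rose by 0.93 (adjusted p = 0.0231). The remaining members that changed, named after their values were seen, were hey1 (-0.60) and nrarpa (0.35). Of 24 sterol synthesis genes, 2 rose, 1 fell and 21 did not pass, also when adjusted over the list alone. Their median was 0.02, their mean -0.02 and the direction of the camera test downward (adjusted p = 0.923). The synthase gene hmgcs1 fell by 0.73 (adjusted p = 0.00056), and the sterol sensor gene insig1 and the receptor gene ldlr rose by 0.68 (adjusted p = 0.00149) and 0.76 (adjusted p = 0.00906).

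Calls among these members also ended when a single library was left out. Without wild-type replicate 1 the calls of epha2 (0.82), cntn1b (-0.65) and dkk1b (0.79) ended. Without wild-type replicate 2 those of epha2 (0.86), cntn1b (-0.59), dkk1b (1.03), her4.1 (-0.84) and ldlr (0.56) ended, and without EWSR1-ERG replicate 1 that of dkk1b (0.68).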

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

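Of the alternatives, 3 were chosen only after the data had been seen, namely EWSR1-ERG replicate 3 thinned to the mean total of the other 5 libraries, the deposited size factors, and leaving out mitochondrial, ribosomal protein and overlapping genes.  Under all settings, 0 of the genes called here reversed direction. The number of higher and lower genes stayed within 1.5 times 1309 and 1732 under other scalings (1268 to 1335 and 1575 to 1753), other filters (1308 to 1466 and 1762 to 1863), DESeq2 (996 and 1375), limma-voom (1191 and 1711), a replicate block (1066 and 1482), no robust estimation (1308 and 1711), thinning (1330 and 1721) and genes left out (1302 and 1716). Tested against 1.5-fold, the counts dropped to 294 and 484, as a stricter null hypothesis requires. Leaving out 1 library gave 646 to 1334 higher and 981 to 1668 lower genes. The counts moved by over 1.5 times without wild-type replicate 1 (718 and 1135) and wild-type replicate 2 (646 and 981). Leaving out any other library gave 1031 to 1334 higher and 1432 to 1668 lower genes, so fewer samples alone do not account for this. Wild-type replicates 1 and 2 had the lowest chi-square per gene of the wild-type pairs (1.72, against 7.12 and 4.79). Whether this lowers the counts was not tested. Of 104 named genes that were called, 78 kept their call in every setting, 12 lost it only against 1.5-fold and 14 lost it without 1 library. The direction of ewsr1a, which was not called, ran from -0.022 without EWSR1-ERG replicate 3 to 0.12 without EWSR1-ERG replicate 2; the cause was not tested. Between 18 and 21 lists were shifted in all settings except fry, with 16, and camera with an estimated correlation, with 0 (6 lists at an unadjusted p under 0.05); the cause was not tested. Beyond that setting, 6 list calls were lost, and 7 lists that were not shifted became so in some setting. No list median changed sign under another scaling. The planned test of transcripts was not run because the files hold genes, and DESeq2, the 1.5-fold test and the fit without robust estimation give no list test here. Depth limits genes near the floor of 0.225 to 0.629 CPM, such as il1b, fosl1a and isg15 in wild-type pools.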

Other observations

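The families and groups in this part, the splits of the libraries and every test except those on mitochondrially encoded genes were chosen only after the results had been seen. Of 18 cathepsin genes, which encode lysosomal proteases, 14 rose and 1 fell, with a median log2 fold change of 1.11 (camera adjusted p = 9.19e-09 over 12 families, adjusted p = 0.348 with an estimated correlation). The cathepsin L gene ctsla rose from 901 to 2418 CPM, and ctsbb was the lower one (-2.16). Of 21 complement genes, 7 rose and 1 fell, with a median of 0.17 (camera adjusted p = 0.000194, adjusted p = 0.183 with an estimated correlation). They were c6.2, c6.1 (2.77), c7a (2.61), cfb (1.92), c3a (1.86), c9 (0.98) and c5 (0.40), and masp2 was the lower one (-0.50). Of 33 aminoacyl-tRNA synthetase genes, which charge tRNAs for translation, 12 rose, with a median of 0.31 (camera adjusted p = 0.000787, adjusted p = 0.469 with an estimated correlation), among them iars (0.99), yars (0.80) and aars (0.65). Of 47 proteasome genes psmd13 alone passed (0.40), with a median of 0.23 (camera adjusted p = 9.04e-05, adjusted p = 0.59 with an estimated correlation). Among 85 ribosomal protein genes rps27.2 (1.36) and rpl7l1 (0.36) rose, with a median of 0.05 (camera adjusted p = 0.136).

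Of 46 Hox genes 10 fell, with a median of -0.07 (camera adjusted p = 0.0999, adjusted p = 0.643 with an estimated correlation). All 10 stand among the 22 tested genes of paralog groups 9 to 13, whose median was -0.57. Of the 24 tested genes of groups 1 to 8, edgeR called 0 and 7 had an unadjusted p under 0.05, with a median of 0.23. The boundary between these groups was chosen after the values were seen, so the difference between them was not tested. The posterior genes hoxb13a (-3.36, adjusted p = 2.24e-05), hoxc13a (-2.35, adjusted p = 0.000175) and hoxc12a (-1.72, adjusted p = 0.00132) fell most. Among 47 voltage-gated channel genes, 6 fell and cacna1sb rose (camera adjusted p = 0.000841, adjusted p = 0.469 with an estimated correlation). Of 53 collagen genes 14 fell and 3 rose, col12a1b (0.55), col17a1b (0.54) and COL19A1 (1 of 4) (0.95), with a camera adjusted p of 0.0864. Of 15 keratin genes 6 fell and 3 rose, krt18 (1.06), KRT18 (2 of 3) (0.78) and krt8 (0.56), with a camera adjusted p of 0.212. Of 14 matrix metalloproteinase genes mmp9, mmp14b (0.52) and mmp2 (0.50) rose and mmp17b (-1.01) and mmp23bb (-0.92) fell, with a camera adjusted p of 0.212. Of these genes, 13 collagen, 8 keratin, 2 cathepsin, 2 metalloproteinase, 1 complement and 1 channel genes also stand in the fixed lists. By fry, only the complement (adjusted p = 0.000445) and cathepsin families (adjusted p = 0.00471) passed. The proteasome (fry adjusted p = 0.177), synthetase (0.0682) and channel families (0.0706), which camera called, did not. Nor did the nuclear oxidative phosphorylation (0.056) and mitochondrially encoded genes (0.0671) described below.

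The 6 libraries can be split into 3 and 3 in 10 ways, the real split included, which is too few for a share under 0.05. The real split was the 1 split with 1309 higher genes and the 1 with 1732 lower genes; the highest other split had 0 of either by edgeR, with 181 to 1027 genes at an unadjusted p under 0.05 against 5284, and 4 calls at most by DESeq2 against 2371. For lists shifted by camera, the real split gave 18, the highest other gave 22, and 4 of 10 splits gave 18 or more. Every other split puts pools of both genotypes into each of its groups. A difference between the genotypes then widens the spread within these groups, which by itself lowers the number of genes called. Part of that difference can also remain between the groups, so the other splits do not show what chance alone would give.

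Mitochondrially encoded genes were lower in EWSR1-ERG pools: 17 of 34 fell, with a median of -0.48 (camera adjusted p = 7.92e-08, adjusted p = 0.469 with an estimated correlation). The choice among the scalings used does not account for the lower values, since the highest median under the other scalings was -0.46. These scalings differed little, with a median over all tested genes from -0.0022 to 0.016. An error of scaling shared by all of them therefore stays open. A lower expression of oxidative phosphorylation genes as a whole is a candidate explanation. Of 102 nuclear genes of that pathway, assembly factors included, 48 fell and ATP5J (3 of 4) rose. Their median was -0.35 (camera adjusted p = 2.3e-12, adjusted p = 0.469 with an estimated correlation, fry adjusted p = 0.056). The 95% bootstrap interval over genes ran from -0.37 to -0.33 (10000 resamples). It treats the genes as independent and does not measure the spread between pools. What lowers the mitochondrially encoded and these nuclear genes, including a different mix of cells in the embryos, was not tested.

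Most photoreceptor genes and 23 of 40 liver, gut and pancreas genes were lower, while 7 of these 40, among them fgg, fga, fgb, cp and apobb, were higher; a delay of the whole embryo and library scaling were weighed for the lower genes. The choice among the scalings does not account for the lower photoreceptor genes. Over the 38 tested by edgeR the median was at most -2.36 under the other scalings, and over the 39 that DESeq2 tests it was -2.34. Since these scalings differed little, an error shared by all of them stays open here too. A delay may contribute to the lower genes and cannot be told apart from a direct effect here, and it was not weighed for the higher ones. The lens list, whose genes accumulate over the same days, had a mean log2 difference of 0.0727, but its standard error of 0.306 between libraries left a moderate delay open, against -2.24 (standard error 0.122) for photoreceptors. An effect of EWSR1-ERG on these cells stays open and was not tested.

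The rise of hbbe3 from 2, 1 and 4 counts to 850, 288 and 1584 was weighed against 3 explanations. More red blood cells are argued against as its whole cause, since the highest log2 fold change among the other erythroid genes was 1.49, with a median of 0.68. Reads shared with other beta globin genes in the same proportion in both groups are argued against too. The share of hbbe3 in the summed beta globin level was 147-fold higher, at 2.61% against 0.0177%. On the log2 scale hbbe2 stood at 0.21, and HBE1 (0.86) and hbbe1.1 (0.50) rose. At 101 CPM in EWSR1-ERG pools, hbbe3 lay below the wild-type SDs of HBE1 (124 CPM) and hbbe1.1 (314 CPM). A loss of that size from them could go unseen, so a sharing that differs between the groups stays open. A haplotype of chromosome 12 that differs between the sorted siblings may account for the rise of hbbe3. It cannot be told apart from an effect of the fusion protein. Of tested chromosome 12 genes 19.3% changed, against 17.2% elsewhere (Fisher's exact test, adjusted p = 0.69), and the labels give no genotype by chromosome.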
